A study of Homo sapiens with 5 samples.

How the data were processed

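Total RNA of WI-38 cells, which are human diploid lung fibroblasts, was sequenced in 5 libraries. Per the labels, the groups were cells at population doubling level (PDL) 15, cells at PDL 55, and cells at PDL 15 that had received siRNA against AUF1, siRNA against HuR, or a control siRNA. Each group had 1 library, so there are no replicates, no p-values and no measure of the spread within a group. Per the labels' protocols, RNA was extracted with Trizol, amplified as cDNA by single-primer isothermal amplification with NuGEN Ovation RNA-Seq reagents, which cover RNA with and without a polyA tail, and sequenced on an Illumina Genome Analyzer. Strand was not stated, so reads of a gene and an overlapping or antisense gene cannot be told apart.

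Per the submitters' processing notes, the tools were TopHat2 2.0.6, Cufflinks 2.0.2 and Cuffdiff, with the build hg19. The authors deposited 1 table per library in which, per the file headers, each transcript has an FPKM value (fragments per kilobase of transcript, scaled to library size), its lower and upper 95% bounds, a coverage value and a status. The deposited coverage is a depth signal along the transcript. The tables list annotated Ensembl transcripts and transcripts assembled from the reads. The annotation release and the number of reads per library are not given in the sources used here.

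Transcripts were assigned to genes from the gene identifiers in the tables, then from GENCODE release 29, which was used for identifiers, gene types, transcript length and GC content only, then from a shared gene identifier or from position. A transcript was assigned by position when at least 50% of its span lay in 1 gene and less than 10% in any other. Of 160485 annotated transcripts, 98.7% received a gene. FPKM was summed over the transcripts of a gene symbol. The bounds were summed likewise, which tends to make them wider than an interval of the sum. They describe the estimate within 1 library, and few genes at least 2-fold apart had overlapping intervals. Intervals did not overlap for 650 of 661 higher and 1935 of 1962 lower genes at PDL 55 against PDL 15. For control siRNA against PDL 15 they did not for 675 of 823 and 2474 of 2550. Genes with a transcript of status FAIL in any library were left out. The plan made before the data were examined was to leave out genes with a status other than OK, on the assumption of a status per gene. The tables give a status per transcript, so transcripts of status LOWDATA were kept and their removal is an alternative. Small RNA genes were left out and counted apart. Genes with a mean FPKM of at least 1 over the 5 libraries were kept, 13028 in all, of which 10343 are protein coding. A gene was called fused when transcripts spanning several genes held over 10% of its own FPKM, which applied to 554 genes. An FPKM of exactly 0 can be a failed estimate, and 758 of the genes kept were listed at 0 in at least 1 library.

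Ratios were computed as log2((FPKM + 1)/(FPKM + 1)), a scale that understates differences of genes at low levels. Genes at least 2-fold apart on it were counted. The deposited scaling moved the median ratio of all genes away from 0, so ratios of genes and lists are given relative to that median unless stated. The 5 comparisons were PDL 55 against PDL 15, each knockdown against control siRNA, AUF1 siRNA against HuR siRNA, and control siRNA against PDL 15. The last served as the background, because neither library had a named knockdown. For 26 gene lists fixed before the data were examined, the median ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean log2(FPKM + 1). A list stood apart when its percentile was under 2.5 or over 97.5, which describes these libraries. The 26 lists cover S phase, mitosis, histones, DNA repair, p53 targets, senescence-associated secreted factors, cell cycle regulators, extracellular matrix, contractile genes, interferon-stimulated genes, NF-kB and immediate early genes, mRNAs bound by AUF1 or HuR, mRNA-binding proteins, ribosomal proteins, translation factors, cholesterol synthesis, glycolysis, the respiratory chain, mitochondrially encoded mRNAs, unfolded protein stress, the lysosome, long noncoding RNAs, and epithelial, endothelial, blood and mesenchymal markers. No mitochondrially encoded mRNA was measured (0 of 13), so 25 lists have a value.

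The genes named were set by a rule written before the data were examined. For each of the 3 main comparisons it takes the 10 highest and 10 lowest ratios among genes with a mean FPKM of at least 5, a 2-fold difference, 95% intervals that do not overlap, a 1.5-fold difference in the same direction against the other PDL 15 library without a knockdown, and a symbol that is neither clone-based nor a pseudogene. For the other comparisons it takes 5 and 5 without the part on the other library. It adds HNRNPD and ELAVL1, and the 3 leading members of each list that stood apart. The rule allowed up to 2 members of the other lists. None were named under that part, a choice made after seeing that many of them changed direction between settings. Sex-linked genes of chromosome Y and the X-inactivation transcripts were left out of the naming and the gene tables. Some genes that the rule selects are not reported. Genes named outside the rule are marked as such.

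Simulated libraries with the spread of AUF1 siRNA against HuR siRNA, 13028 genes, were used to test the computations. Of 1000 lists of 40 genes with no shift, 4% stood apart, and 100% did with a log2 shift of 0.5. These lists were random sets of genes simulated independently of each other, so the 4% follows largely from the percentile cut. Genes of a fixed list can vary together, so that rate does not carry over to the fixed lists. Of 200 genes made 2-fold higher, 37% came out at least 2-fold higher, against 86% of those made 4-fold higher and 99.5% of those made 8-fold higher. About 4.08% of the unchanged genes came out at least 2-fold apart. The observed shares relative to the median gene were higher, at 8.58% for AUF1 siRNA against HuR siRNA and 19.8% for control siRNA against PDL 15. The simulated rates therefore check the computations and are not error rates of the comparisons reported here. Correlations between comparisons that share a control were set beside those of 100 simulated sets of unchanged libraries.

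The 11 alternatives listed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, a median ratio set to 0, quantile normalization, inclusion of small RNA genes, non-overlapping intervals, a 1.5-fold threshold, 1 transcript per gene, and the other PDL 15 library as the control. The 6 chosen after seeing the data were annotated transcripts only, fragment mass (FPKM times transcript length), removal of LOWDATA transcripts, removal of genes with any status other than OK, removal of genes at 0 or in fused loci, and a correction for GC content and length. A count was held to be alike when within 1.5 times the first value and a correlation when within 0.1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.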

Results

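The 5 WI-38 libraries ask what differs between early- and late-passage fibroblasts and after knockdown of the RNA-binding proteins AUF1 and HuR, which bind AU-rich sequences in mRNAs. Each group had 1 library, so no difference below has a replicate check, and every count compares 2 libraries rather than 2 conditions. Depth in reads was not stated. The coverage per unit FPKM, which scales with depth, was 1.26 at PDL 15, 1.29 at PDL 55, 1.25 with AUF1 siRNA and 1.14 with HuR siRNA, but 0.300 with control siRNA. In that control library 76.6% of FPKM times length lay in assembled transcripts without a gene, and 73.8% in those under 100 nt. The share without a gene was 11.3% at PDL 15, 15.6% at PDL 55, 13.6% with AUF1 siRNA and 15.0% with HuR siRNA. FPKM is unreliable for features shorter than a fragment, so these need not be shares of reads.

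The siRNA targets were read first. HNRNPD, the gene of AUF1 (ENSG00000138668, hg19 chromosome 4, 83273651 to 83295656), had an FPKM of 20.3 with AUF1 siRNA (95% interval 16.7 to 24.0) and 61.2 with control siRNA (48.0 to 74.4), a log2 ratio of -1.54, or -1.73 relative to the median gene. It was 119 at PDL 15, 120.3 with HuR siRNA and 42.3 at PDL 55. Among its annotated transcripts, ENST00000307213 was at 6.94 with AUF1 siRNA and 23.4 with control siRNA, and ENST00000509263 at 9.90 and 17.7. In the same order, ENST00000353341 was at 0 and 8.57 and ENST00000513584 at 0 and 11.5, while ENST00000543098 was higher, at 3.50 and 0. With 1 transcript for the gene the ratio was -0.78. ELAVL1, the gene of HuR (ENSG00000066044, hg19 chromosome 19, 8023458 to 8070529), had an FPKM of 9.72 with HuR siRNA (8.59 to 10.8) and 11.8 with control siRNA (9.38 to 14.1). These intervals overlap, and the log2 ratio was -0.25, or -0.56 relative to the median. ELAVL1 was 16.6 at PDL 15, 12.2 at PDL 55 and 17.7 with AUF1 siRNA, and its ratio of HuR siRNA to PDL 15 was -0.72.

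The comparison of PDL 55 with PDL 15 asks what differs in late-passage fibroblasts. Genes of cell division were much lower in the PDL 55 library. Of 50 measured mitosis genes, 44 were at least 2-fold lower and 0 higher relative to the median gene, and the list median was -2.24 on the log2 scale (percentile 0 of matched random lists). MKI67, a proliferation marker, was at 0.503 FPKM against 28.2, ANLN, a cytokinesis protein, at 6.03 against 103, and FOXM1, a transcription factor of mitotic genes, at 0.310 against 13.8. The S phase list had a median of -1.01, with 19 of 38 genes at least 2-fold lower, among them the nucleotide synthesis genes RRM2 (log2 ratio relative to the median gene, as for the genes that follow, -3.66) and TK1 (-2.58) and the clamp loader RFC3 (-2.24). DNA repair genes had a median of -0.52, led by BARD1 (-2.18), EXO1 (-2.14) and BRIP1 (-1.66). HIST1H1E, a linker histone, was at 1.34 against 41.8. The histone list had a median of -0.20 (percentile 10.9) against PDL 15 and -1.61 (percentile 0) with control siRNA as the reference. In every comparison 24 of its 60 genes were measured, and most others had no matching row, so its medians do not cover the whole family.

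Extracellular matrix genes were also lower at PDL 55. Of 40 measured, 19 were at least 2-fold lower and 3 higher, with a list median of -0.90 (percentile 0). FBLN1, a matrix glycoprotein, was at 7.46 FPKM against 304, TNC, the matrix protein tenascin C, at 13.3 against 292, and POSTN, periostin, at 8.30 against 155. Mesenchymal fibroblast markers had a median of -0.89, with COL3A1 at -2.58, TBX4 at -2.23 and PRRX1 at -2.16. Other genes among the 10 lowest were TNFRSF19, a receptor of the tumour necrosis factor family (-4.69), the glypican GPC6 (-4.40), the noncoding RNA CARMN (-4.25), PCOLCE, an enhancer of procollagen processing (-4.25), the complement protease C1R (-4.23) and ABI3BP (-4.02). With control siRNA as the reference the matrix median was -0.53 and that of mesenchymal markers -0.46. The ratios of the genes named in this paragraph were also smaller in size with that reference. As deposited, FBLN1 was -5.17 against PDL 15 and -2.18 against control siRNA, and TNC -4.35 and -1.70. Likewise PCOLCE was -4.56 and -2.58, C1R -4.54 and -1.19, and GPC6 -4.72 and -3.80. Among genes without any LOWDATA or FAIL transcript, the matrix median turned to 0.17.

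The medians of the secreted and lysosomal lists were higher at PDL 55. The senescence-associated secreted factors had a median of 0.62 (percentile 100), with 11 of 31 measured genes at least 2-fold higher and 4 lower. The list holds 52 genes. Those not measured include CXCL8, IL1A, IL1B and CXCL1 (mean FPKM under 1) and MMP1 and MMP3 (status FAIL). IGFBP7, which binds insulin-like growth factors, was at 357 FPKM against 24.6, the glycoprotein hormone STC1 at 180.3 against 24.7, and the protease inhibitor SERPINB2, in a fused locus, at 15.8 against 1.76. Lysosomal genes had a median of 0.64 (percentile 100), with FUCA1 at 1.90 and the cholesterol transporter NPC1 at 1.62. CCND2, cyclin D2, was at 65.6 against 1.40, and its antisense neighbour CCND2-AS1, whose reads cannot be separated from it, at 24.6 against 0.947. WNT16, a Wnt ligand, stood at 4.02, the pregnancy-specific glycoprotein PSG9 at 3.81, NABP1, a single-stranded DNA binding protein, at 3.86, SPSB3 at 4.10, CCDC68 at 3.79 and RNF217-AS1 at 3.92. C9orf131 had the highest ratio (4.88 as deposited), which turned to -1.53 on annotated transcripts alone.

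Smaller list differences were seen at PDL 55. Respiratory chain genes had a median of 0.35, led by NDUFA1 (1.29), NDUFC2 (0.93) and NDUFS7 (0.90). Glycolysis and hypoxia genes had a median of 0.43, and their percentile was 79.4 with control siRNA as the reference. Their leading genes NDRG1 (2.81), the hexokinase HK2 (2.39) and LDHA (1.72) each turned lower in other settings, with deposited ratios of -3.10 and -0.55 on annotated transcripts alone and -0.65 without LOWDATA transcripts. The p53 targets had a median of 0.30 (percentile 98.0, 96.3 with control siRNA as the reference), led by PERP (3.12), the cell cycle inhibitor CDKN1A (1.58) and PLK3 (1.39, but -0.15 as deposited with 1 transcript for the gene). NF-kB and immediate early genes had a median of -0.31, with EGR1 at -2.32, TNFAIP3 at -1.75 and NFKBIA at -1.19, and the median turned to 0.15 among genes with a mean FPKM of at least 5. The mRNA-binding proteins had a median of -0.30, with CIRBP, in a fused locus, at -2.41, HNRNPA1 at -1.45 and HNRNPF at -1.40. HNRNPD, which is not on that list, was at -1.16. Ribosomal protein genes had a median of -0.39 against PDL 15, with RPS9 at -1.08, RPL3 at -1.04 and RPS15A, in a fused locus, at -3.23, but 0.58 with control siRNA as the reference. RPS15A turned to 5.90 on annotated transcripts alone. Besides histones, the lists that did not stand apart were cell cycle regulators (-0.31), contractile genes (0.045), interferon-stimulated genes (0.11), mRNAs bound by AUF1 or HuR (-0.082), translation factors (0.12), cholesterol synthesis (0.25), unfolded protein stress (-0.083), long noncoding RNAs (-0.29), and epithelial (-0.00030), endothelial (0.32) and blood markers (-0.14). Of these, translation factors (0.72, percentile 99.9) and cholesterol synthesis (1.05, percentile 100) stood apart with control siRNA as the reference, and unfolded protein stress (-0.31, percentile 1.77) and histones (-0.34, percentile 1.14) did on fragment mass. NDUFC2 was -0.27 as deposited with 1 transcript for the gene.

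In all, 661 of 13028 genes were at least 2-fold higher and 1962 lower in the PDL 55 library as deposited. Of these, 118 and 185 were listed at 0 in 1 of the libraries, which can be a failed estimate. The median log2 ratio was -0.32, and relative to it 1060 were higher and 1107 lower. With control siRNA as the reference, the mitosis median was -2.55, the S phase median -1.51 and the secreted factor median 0.77. Single genes that lost their 2-fold difference as deposited with that reference included NFKBIA (0.14), RPS9 (0.39) and RPL3 (0.42), which turned higher, and POSTN (-0.94), COL3A1 (-0.25), TNFAIP3 (-0.71), CIRBP (-0.46), HNRNPA1 (-0.65), HNRNPF (-0.48), HNRNPD (-0.52), SERPINB2 (0.60) and PLK3 (0.67).

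Control siRNA against PDL 15 gives the background of the knockdown comparisons, since neither library had a named knockdown. Translation and matrix genes were lower in the control siRNA library and histone genes higher. Ribosomal protein genes had a median of -0.98, with 34 of 70 at least 2-fold lower, among them RPL4 (-2.30) and, in fused loci, RPL7A (-2.47) and RPS15A (-4.45). Translation factors had a median of -0.48, led by the elongation factor EEF1A1 (-1.64), EIF4A2 (-1.49) and EIF4A3 (-1.33). Matrix genes had a median of -0.76, with POSTN at -2.72, FBLN1 at -2.58 and COL14A1 at -2.37, mesenchymal markers -0.62, with COL3A1 at -2.24, DCN at -2.23 and LUM at -1.75, and contractile genes -0.63, with FLNA at -1.92, PDLIM7 at -1.60 and ACTG2 at -1.49. Cholesterol synthesis genes had a median of -0.43, with CYP51A1 at -2.42, FDPS at -1.52 and IDI1 at -1.47, and respiratory chain genes -0.38, with NDUFA9 at -2.09, NDUFA8 at -1.51 and UQCRC1 at -1.48. Histone genes had a median of 1.41, with HIST1H2BL at 4.92, HIST1H2AD at 3.65 and HIST2H2AC at 2.40. Higher medians were also found for NF-kB and immediate early genes (0.50; FOSL1 2.22, JUND 2.01, DUSP5 1.06), glycolysis (0.35, but -0.12 on annotated transcripts; GPI 1.03, and PFKP 1.03, which was -0.48 as deposited on fragment mass) and mitosis (0.32), where PTTG1 stood at 2.73, UBE2C at 2.56 and BIRC5 at 1.88. Single genes had a summed FPKM far above that in the other libraries, such as DLG2 (950.2 FPKM against 33.2) and NELL1 (51.5 against 1.03). Those of KIAA1522 (1871 against 4.00) and MLF2 (1344 against 40.7) rest on assembled transcripts, and on annotated transcripts alone their deposited ratios were -0.10 and -5.38. The lowest after RPS15A were SURF4 (-3.74), ARSG (-3.25), POLR2H (-3.16) and RNF169 (-3.07), but on annotated transcripts RPS15A (4.83), SURF4 (0.12) and ARSG (1.43) were higher as deposited. Without LOWDATA transcripts PTTG1 turned to -3.32, UQCRC1 to 0.53 and DUSP5 to -0.27, and on fragment mass SURF4 (-0.95), BIRC5 (0.80) and PDLIM7 (-0.71) lost their 2-fold difference as deposited. As deposited, 823 genes were at least 2-fold higher and 2550 lower, with a median log2 ratio of -0.41, and 1466 and 1110 relative to it. Of the deposited counts, 174 and 220 were listed at 0 in 1 of the libraries. This background involves 19.8% of genes, against 15.8% for AUF1 siRNA and 16.8% for HuR siRNA against control siRNA.

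AUF1 siRNA against control siRNA asks which RNAs differ when AUF1 is reduced. CDKN1A, the cell cycle inhibitor p21 and a target of p53, was at 392 FPKM against 74.2 with control siRNA and 145 at PDL 15. The p53 targets had a median of 0.40 (percentile 99.0), with GDF15, a stress cytokine, at 17.1 against 3.04 and PLK2 at 0.97, which turned to -1.01 as deposited against PDL 15. With PDL 15 as the reference, the p53 median was 0.37 (percentile 99.0), but on fragment mass its percentile was 58.8, and without LOWDATA transcripts the median was 0.020, on the lower side of matched lists. Ribosomal protein genes were lower than random lists matched on level (percentile 0.220), though their median of 0.032 was near that of all genes. Of 70 measured, 13 were at least 2-fold lower and 3 higher, with RPL29 at -1.71 and RPL34 at -1.70. With PDL 15 as the reference their median was -0.97. Control siRNA against PDL 15 had -0.98, so that value does not set AUF1 siRNA apart. Matrix genes had a median of 0.72, with COL12A1 at 2.56, TNC at 1.55 and FBLN2 at 1.52, contractile genes 0.56, with FLNA at 1.66, TGFBI at 1.51 and PDLIM7 at 1.38, and histone genes -0.53, with HIST1H2BL at -3.70, HIST1H2AD at -2.51 and HIST1H4C at -2.34. With PDL 15 as the reference these medians were 0.10, -0.23 and 0.48, so 2 of the 3 changed direction. On fragment mass COL12A1 (0.70), TNC (0.31), FBLN2 (-0.0080), TGFBI (0.83), PDLIM7 (0.80) and PLK2 (0.79) lost their 2-fold difference as deposited. TNC (-0.92), FBLN2 (-0.70), FLNA (-0.48), TGFBI (-0.042) and PDLIM7 (-0.44) were likewise lower, and HIST1H2BL (1.004) and HIST1H2AD (0.92) higher, as deposited against PDL 15, and COL12A1 (0.12) and HIST1H4C (-0.80) less than 2-fold apart. With that reference, mitosis (0.46), secreted factors (0.42), glycolysis (0.44) and epithelial markers (0.78, 4 genes measured) also stood apart as higher. Cholesterol synthesis (-0.51), the respiratory chain (-0.28) and mesenchymal markers (-0.54) did as lower. None of these lists stood apart against control siRNA. Control siRNA against PDL 15 itself had 0.32 for mitosis, 0.35 for glycolysis and 0.25 for epithelial markers. It had -0.43 for cholesterol synthesis, -0.38 for the respiratory chain and -0.62 for mesenchymal markers. Secreted factors had 0.011 there.

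Single genes with the highest ratios after AUF1 siRNA included UCP2, a mitochondrial carrier, at 104 FPKM against 17.0. Others were the lipase ABHD4 at 93.4 against 13.6 and PPIF, the mitochondrial cyclophilin, at 49.5 against 7.80. ZSWIM8 was at 29.6 against 3.17 and KIRREL3-AS2 at 22.1 against 3.08. In fused loci, CLDN11, a claudin, was at 152 against 24.5 and RBM27 at 15.7 against 1.10. As deposited, CLDN11 was 2.59 against control siRNA and 1.03 against PDL 15, and ZSWIM8 2.88 and 1.35. Likewise ABHD4 was 2.69 and 1.86 and PPIF 2.52 and 1.64, while UCP2 was 2.55 and 2.57. FMN1 had a deposited log2 ratio of 3.10 but 0.49 on fragment mass. NUBP2 (4.27) and B3GALT6 (3.63) turned to -1.46 and -0.33 on annotated transcripts alone. FHIT, a gene at a fragile site, was at 1.46 against 19.4. Other low genes were SLC35E2B, in a fused locus (-3.92), and HFM1 (-3.62), at 758 FPKM against 8200 and 1199 at PDL 15. The transporter SLCO5A1 (-3.07), the protease PCSK5 (-2.93), CHODL (-2.83), NR3C2, the mineralocorticoid receptor (-2.62), and the adhesion gene OPCML (-2.60) were also low. MUC20-OT1, in a fused locus, had a deposited ratio of -2.89 that was -0.011 on fragment mass. NR3C2 was -0.94 there, and against PDL 15 HFM1 (-0.66), SLCO5A1 (-0.78) and PCSK5 (-0.87) were less than 2-fold apart as deposited. Of the mRNAs described elsewhere as bound by AUF1 or HuR, 32 of 50 were measured, and the list did not stand apart (0.21, percentile 79.5). Relative to the median, 4 were at least 2-fold higher and 3 lower, and a list median does not show changes in opposite directions. As deposited, 1377 genes were at least 2-fold higher and 894 lower, with a median log2 ratio of 0.19, and 899 and 1163 relative to it. Of the deposited counts, 195 and 178 were listed at 0 in 1 of the libraries.

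HuR siRNA against control siRNA asks the same of HuR. Measured secreted factors had a higher median in the HuR siRNA library. Their median was 0.73 (percentile 100), with 8 of 31 at least 2-fold higher and 2 lower, and 0.88 with PDL 15 as the reference. GDF15 was at 20.2 FPKM against 3.04 and IGFBP5 at 372 against 93.0, though IGFBP5 turned to a deposited log2 ratio of -6.55 on annotated transcripts alone. Cholesterol synthesis genes were slightly lower as a list, with 1 of 21 at least 2-fold lower and a median of -0.36 (percentile 0.240), or -0.99 with PDL 15 as the reference. They were led by MSMO1 (-1.05), HSD17B7 (2.42 FPKM against 4.51) and HMGCS1, an early enzyme of the pathway (-0.76). The intervals of each overlapped those of control siRNA. The cholesterol synthesis median was -0.43 in control siRNA against PDL 15, so the -0.99 does not rest on HuR siRNA alone. Unfolded protein and amino acid stress genes had a median of 0.47 (percentile 99.6, 95.1 with PDL 15 as the reference), led by the amino acid transporter genes SLC3A2 (2.12) and SLC7A5 (1.25) and by CHAC1 (1.22).

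Most other lists that stood apart did so only against control siRNA. Matrix genes had a median of 0.86 (0.22 with PDL 15 as the reference), with SPARC at 2.24, TNC at 1.89 and COL12A1 at 1.87. Respiratory chain genes had 0.44 (0.016), with NDUFA9 at 2.52 and ATP5F1A at 1.54, which turned to -3.70 as deposited without LOWDATA transcripts. Interferon-stimulated genes had 0.24 (-0.10), with UBE2L6 at 1.08, PSMB9 at 0.92 and IFIT3 at 0.80. Histone genes had -1.37 (-0.077), with HIST1H2BL at -4.48, S phase genes -0.48 (-0.093), with CDC45 at -1.58 and LIG1 at -1.11, mitosis genes -0.34 (0.040), with PTTG1 at -1.51, UBE2C at -1.49 and SPC25 at -1.20, and cell cycle regulators -0.26 (-0.077), with HMGA2 at -1.14, CCND2 at -1.14 and HMGB2 at -0.75. Ribosomal protein genes, led by RPL4 (1.91), RPL7A (1.68) and RPS14 (1.41), had a median of 0.58 against control siRNA and -0.36 against PDL 15, standing apart in opposite directions. Against PDL 15, PTTG1 (1.12), UBE2C (0.97), CCND2 (0.96), LIG1 (0.28) and HIST1H2BL (0.35) were higher as deposited, and TNC (-0.45), COL12A1 (-0.45), RPL4 (-0.48), RPL7A (-0.89) and RPS14 (-0.52) lower. Others were less than 2-fold apart there, including SPC25 (-0.77), HMGA2 (-0.49), HMGB2 (-0.052), CDC45 (-0.28), UBE2L6 (0.47), IFIT3 (0.27), NDUFA9 (0.33), ATP5F1A (0.11) and CHAC1 (0.94). On fragment mass COL12A1 (0.30), TNC (0.73), CDC45 (-0.83), PTTG1 (-0.996) and UBE2C (-0.72) lost their 2-fold difference as deposited. Without LOWDATA transcripts CDC45 turned to 0.19, HMGB2 to 0.072 and PTTG1 to 3.87 against control siRNA, and UBE2C was 1.20 with 1 transcript for the gene. Glycolysis (0.56) and mesenchymal markers (-0.42) stood apart only against PDL 15, where control siRNA itself had 0.35 and -0.62.

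Single genes with the highest ratios after HuR siRNA were AHCTF1 (3.10), RNF25 (3.09), ZNF75A (2.99), SLC35B4 (2.76) and, in a fused locus, RBM27 (2.75). Others were the kinesin light chain KLC1 (2.57), ZSWIM8 (2.54) and TMED1 (2.44). EVC and the caveolin CAV2 had deposited log2 ratios of 3.12 and 2.76, but 0.42 and -0.24 on fragment mass. RNF25 turned to -1.89 without LOWDATA transcripts, and CBX1, among the lowest genes, to 3.74 with 1 transcript for the gene. Among the lowest were CCDC148 (-5.33), at a high level in the control siRNA library alone, CBX1 (-3.70), CHODL (-3.59), FHIT (-3.15), HIST2H2AC (-3.09), AUTS2 (-3.01), HIST1H2AI (-2.64) and ZNF780A (-2.61), whose deposited ratio was -0.42 on fragment mass. Against PDL 15 KLC1 (0.68), CCDC148 (-0.68), HIST2H2AC (-0.79) and HIST1H2AI (-0.62) were less than 2-fold apart as deposited. The mRNAs described elsewhere as bound by AUF1 or HuR did not stand apart (0.073, percentile 31.8). Relative to the median, 3 of 32 measured were at least 2-fold higher and 3 lower. On fragment mass the list was lower (-0.19, percentile 0.350). As deposited, 1910 genes were at least 2-fold higher and 745 lower, with a median log2 ratio of 0.31, and 975 and 1210 relative to it. Of the deposited counts, 197 and 196 were listed at 0 in 1 of the libraries.

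**Figure D1:**
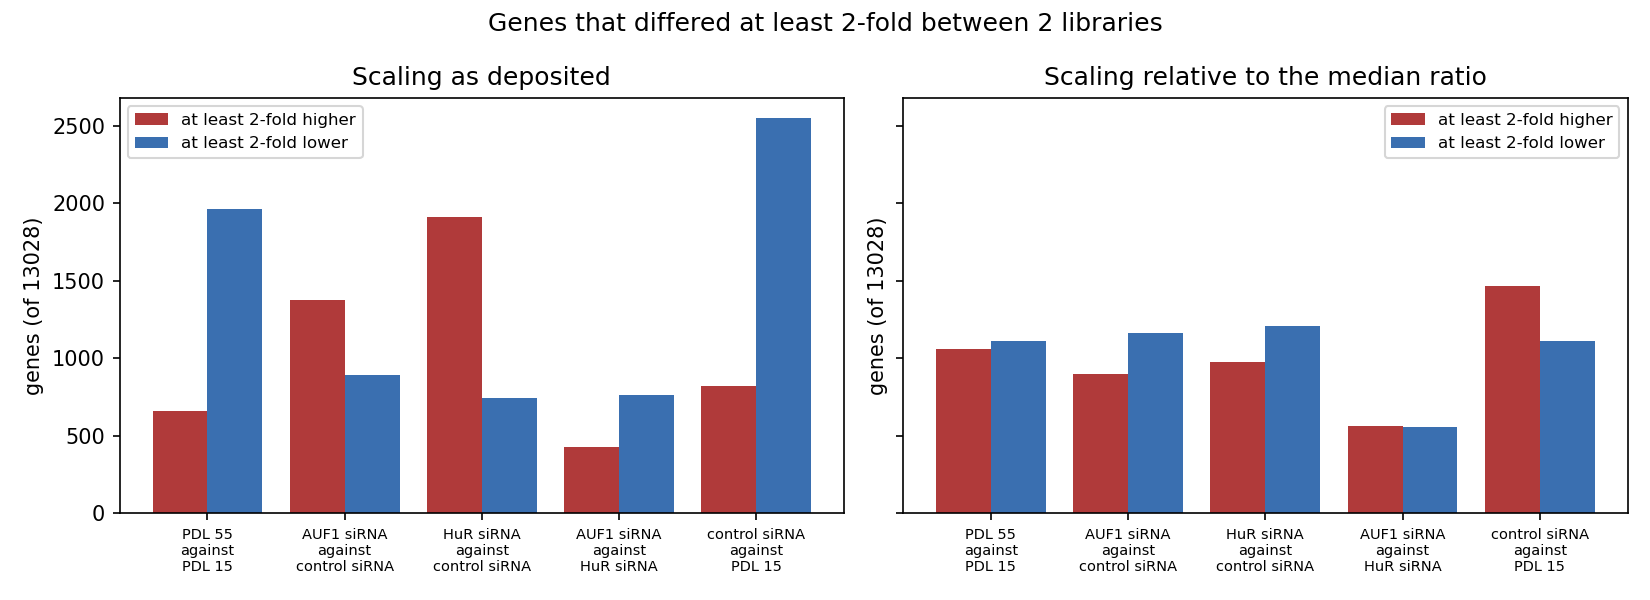
Genes at least 2-fold higher or lower (vertical axis, of 13028) in each comparison of 2 libraries (horizontal axis), with the scaling as deposited and relative to the median ratio. Relative to the median, control siRNA against PDL 15 has 1466 higher and 1110 lower genes, and AUF1 siRNA against HuR siRNA 562 and 556.

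AUF1 siRNA against HuR siRNA compares the knockdowns without the control siRNA library. The median of division genes was higher with AUF1 siRNA than with HuR siRNA, and those of secreted, matrix and ribosomal protein genes were lower, though few members were 2-fold apart. Relative to the median gene, 6 of 50 mitosis genes were at least 2-fold higher and 0 lower, as were 2 and 2 of 38 S phase genes, 1 and 5 of 31 secreted factors, 1 and 5 of 40 matrix genes and 2 and 16 of 70 ribosomal protein genes. The medians were 0.49 for mitosis, with CDC20 at 1.44, PLK1 at 1.29 and MYBL2 at 1.20, 0.28 for S phase, with MCM5 at 1.20, MCM2 at 1.03 and MCM7 at 0.98, and 0.70 for histones, with HIST1H3J at 2.10. Cholesterol synthesis genes had a median of 0.39, with LSS at 1.22 and FDPS at 1.08. The mRNAs described elsewhere as bound by AUF1 or HuR had a median of 0.23 (percentile 99.4), with CASP2 at 1.23, PTMA at 0.84 and CDKN1A at 1.16, and the deposited ratio of CDKN1A, 1.04, turned to -0.26 with 1 transcript for the gene. Epithelial markers, of which 4 were measured, had 0.74, with KRT19 at 11.7 FPKM against 6.10, KRT18 at 6.93 against 4.25 and CLDN4 at 1.53 against 0.611. Secreted factors had a median of -0.53, with the chemokine CCL2 at -1.73, LIF at -1.48 and FGF7 at -1.33. Matrix genes had -0.33, with COL3A1 at -1.84, DCN at -1.34 and POSTN at -1.23, ribosomal protein genes -0.50, with RPL34 at -1.71, RPL26 at -1.63 and RPLP2, in a fused locus, at -1.69, and respiratory chain genes -0.31, with NDUFA9 at -1.06, SDHB at -0.99 and NDUFA4 at -0.99. The highest genes after NUBP2 (3.75) and B3GALT6 (3.22) were GAB2 (3.19), UCP2 (3.07) and FKBP1C (3.02), and the lowest were ZNF814 (-3.71), ZNF75A (-3.18), EVC (-2.99), C1QTNF5 (-2.67) and C16orf72 (-2.54). On annotated transcripts alone NUBP2 (-2.10), B3GALT6 (-0.86), ZNF814 (1.78), C16orf72 (1.63) and LIF (0.14) had the opposite sign as deposited, as had KRT19 (-0.27) and FDPS (-0.00074) without LOWDATA transcripts. On fragment mass EVC (-0.51), B3GALT6 (0.62), ZNF75A (-0.86), C16orf72 (-0.58), LIF (-0.59), CDKN1A (0.27), MCM5 (0.62), LSS (0.46) and SDHB (-0.91) lost their 2-fold difference as deposited. As deposited, 426 genes were at least 2-fold higher and 762 lower, with a median log2 ratio of -0.12, and 562 and 556 relative to it. Of the deposited counts, 125 and 106 were listed at 0 in 1 of the libraries.

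Across genes, which are not independent replicates, 3 relations between changes were computed. The AUF1 siRNA and HuR siRNA ratios against control siRNA had Pearson r = 0.71 and Spearman rho = 0.65, with a covariance of 0.610. Unchanged libraries simulated against the shared control gave r = 0.50 with a covariance of 0.276 from the spread of control siRNA against PDL 15, r = 0.50 with a covariance of 0.119 from that of AUF1 siRNA against HuR siRNA, and r = 0.73 (0.65 to 0.77 in 100 sets) with a covariance of 0.0834 from the deposited intervals. In the first 2 simulations all 3 libraries had the same spread, which fixes r near 0.50 whatever the data. The control siRNA library had a lower coverage per FPKM than the others, so an equal spread may not describe it. The observed r lies within the range of the last simulation, so r alone does not set the knockdowns apart from unchanged libraries. With PDL 15 as the control of AUF1 siRNA alone r was 0.020 (covariance 0.0161), and as that of HuR siRNA alone 0.064 (covariance 0.0490). Relative to the median, 450 genes were at least 2-fold higher in both, of 899 and 975, where independent lists would share 67.3 and the simulated libraries shared 342, 47.1 or 34.3 in the same order. Likewise 708 were lower in both, of 1163 and 1210, against 108 for independent lists and 342, 46.7 or 34.8 simulated. With separate controls the covariance fell from 0.610 to 0.0161 or 0.0490, so most of it depended on the shared control siRNA library. These overlaps were counted with that shared control, so they do not show a response common to both knockdowns. The PDL 55 ratios had r = -0.027 (rho = 0.0031) with those of AUF1 siRNA and r = 0.030 (rho = 0.094) with those of HuR siRNA, comparisons that share no library. Relative to the median, 181 genes were higher at PDL 55 and lower with AUF1 siRNA (94.6 for independent lists), and 88 the reverse (76.4). In both, 105 were higher (73.1) and 113 lower (98.8). For HuR siRNA the same counts were 160 (98.4), 80 (82.8), 128 (79.3) and 152 (102.8).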

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

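The test of the PDL 15 reference for division genes and both tests of ELAVL1 were chosen after the result was seen, and the corrections for GC content and length and for genes at 0 or in fused loci were chosen after seeing the data.

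FPKM times length outside the gene comparisons was high in 1 library. In the control siRNA library 76.6% of FPKM times length lay in assembled transcripts without a gene, above the 11.3% of the PDL 15 library, and 73.8% lay in 282 such transcripts under 100 nt. These transcripts were not analysed here. FPKM is unreliable for features shorter than a fragment, so these values need not be shares of reads.

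More genes differed at least 2-fold between control siRNA and PDL 15, which lack a named knockdown, than between the knockdown libraries. Among genes with a mean FPKM of at least 50, the share that differed was 2.77 times that between AUF1 siRNA and HuR siRNA (26.4% against 9.51%), which argues against shallow sequencing as the whole cause. The ratio of counts was 2.20 after correction for GC content and transcript length and 2.61 without genes at 0 or in fused loci, where 1.5 or less was set as the bound for either as the whole cause. Transfection with control siRNA, which the design names, and a difference in library preparation may each contribute, and neither was tested. With 1 library each, they stay open.

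Mitosis and DNA replication genes were lower in the PDL 55 library. The mitosis median relative to all genes was -2.24 after correction for GC content and transcript length, and -2.55 with control siRNA in place of the PDL 15 library, where a value within 0.5 of the median would have pointed to either as the cause. A lower share of dividing cells at PDL 55 is a hypothesis that these values leave open. Counts of cells in DNA synthesis and in mitosis, in replicate cultures matched for density and day of collection, could decide it and were not used here.

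ELAVL1 was less than 2-fold lower in the HuR siRNA library than in the control siRNA library. Scaling of the control siRNA library does not account for this as a whole, since the log2 ratio was -0.56 relative to the median, short of -1. Exchanged labels of the AUF1 siRNA and HuR siRNA libraries would need HNRNPD to be higher with AUF1 siRNA, and its log2 ratio there was -2.51. A modest reduction of the mRNA, and a reduction of HuR protein that the mRNA does not show, stay open and may not be separated by RNA levels.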

How the results depend on the processing

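The alternatives on annotated transcripts, fragment mass, LOWDATA transcripts, status, genes at 0 or in fused loci, and GC content and length were chosen after seeing the data. Depth in reads was not stated, and no alternative can stand in for a replicate. Counts are given as higher and lower. No count moved by over 1.5 times with small RNA genes included, non-overlapping intervals, annotated transcripts, fragment mass, LOWDATA transcripts left out or the GC and length correction. The cause was not tested for any value below, except that a lower threshold, a smaller gene set or a larger pseudocount alters counts by construction.

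At a 1.5-fold threshold the counts were 1274 and 4292 for PDL 55, 3317 and 1721 for AUF1 siRNA, 4333 and 1448 for HuR siRNA, 1132 and 2276 for AUF1 against HuR siRNA and 1479 and 5132 for the background. With a pseudocount of 5 they were 336 and 856 for PDL 55, 581 and 345 for AUF1 siRNA, 871 and 318 for HuR siRNA, 190 and 339 for AUF1 against HuR siRNA and 342 and 1174 for the background. Without genes of any status other than OK they were 250 and 653 for PDL 55, 477 and 386 for AUF1 siRNA, 684 and 311 for HuR siRNA, 150 and 286 for AUF1 against HuR siRNA and 335 and 931 for the background. A pseudocount of 0.1 gave 659 and 1235 for AUF1 against HuR siRNA. At a mean FPKM of at least 5 the counts were 381 and 1275 for PDL 55, 259 higher for AUF1 against HuR siRNA, 337 higher for the background, and 344 and 269 lower for AUF1 and HuR siRNA. Without a filter they were 1406 higher for the background and 1594 and 1423 lower for AUF1 and HuR siRNA. With the median ratio set to 0 they were 1060 and 1107 for PDL 55, 899 higher for AUF1 siRNA, 975 and 1210 for HuR siRNA and 1466 and 1110 for the background. Quantile normalization gave 1039 and 1089 for PDL 55, 1043 higher for HuR siRNA and 1369 and 1287 for the background. With 1 transcript per gene 2423 genes were higher for AUF1 siRNA and 678 for AUF1 against HuR siRNA, and without genes at 0 or in fused loci the latter was 267. With the other PDL 15 library as the control the counts were 1851 higher for PDL 55, 665 and 1512 for AUF1 siRNA and 758 higher for HuR siRNA. The HNRNPD ratio of AUF1 siRNA was -0.78 with 1 transcript per gene and otherwise ran from -1.90 to -1.27 against control siRNA, and was -2.49 against PDL 15. That of ELAVL1 for HuR siRNA ran from -0.62 to -0.18 against control siRNA, and was -0.72 against PDL 15.

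The correlation of AUF1 and HuR siRNA ratios was 0.020 with PDL 15 as the control of AUF1 siRNA, 0.064 with it as that of HuR siRNA and 0.64 with it as that of both. With PDL 15 shared, PDL 55 had 0.37 with AUF1 siRNA and 0.44 with HuR siRNA, and with control siRNA shared 0.53 and 0.59.

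Several lists changed direction. With the other PDL 15 library as the control, these were ribosomal proteins for PDL 55 (0.58) and HuR siRNA (-0.36), histones (0.48) and contractile genes (-0.23) for AUF1 siRNA, and mitosis (0.040) and interferon-stimulated genes (-0.10) for HuR siRNA. For PDL 55, NF-kB genes had 0.15 at a mean FPKM of at least 5 and 0.0043 with 1 transcript per gene, and matrix genes 0.17 without genes of another status than OK. That setting gave 0.0067 for contractile genes with AUF1 siRNA and -0.093 in the background. Without LOWDATA transcripts the p53 targets of AUF1 siRNA lay on the other side of matched lists (0.020), and on annotated transcripts glycolysis in the background had -0.12.

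Some named genes at least 2-fold apart as deposited changed sign, each with the deposited log2 ratio of that setting. With 1 transcript per gene these were, for PDL 55, C9orf131 (-1.22), PLK3 (-0.15), RPS15A (5.90) and HK2 (-0.55); for AUF1 siRNA, NUBP2 (-0.93) and B3GALT6 (-0.33); for HuR siRNA, EVC (-0.22), CBX1 (3.74) and UBE2C (1.20). For AUF1 against HuR siRNA they were NUBP2 (-1.96), B3GALT6 (-0.86), ZNF814 (1.78), C16orf72 (1.63), LIF (0.14) and CDKN1A (-0.26), and in the background KIAA1522 (-0.099), MLF2 (-3.69), RPS15A (4.83), SURF4 (0.12) and ARSG (1.43). On annotated transcripts alone they were, for PDL 55, C9orf131 (-1.53), RPS15A (5.90), NDRG1 (-3.10) and HK2 (-0.55); for AUF1 siRNA, NUBP2 (-1.46) and B3GALT6 (-0.33); for HuR siRNA, EVC (-0.22) and IGFBP5 (-6.55). For AUF1 against HuR siRNA they were NUBP2 (-2.10), B3GALT6 (-0.86), ZNF814 (1.78), C16orf72 (1.63) and LIF (0.14), and in the background KIAA1522 (-0.10), MLF2 (-5.38), RPS15A (4.83), SURF4 (0.12) and ARSG (1.43). Without LOWDATA transcripts they were PLK3 (-0.15) and LDHA (-0.65) for PDL 55, RNF25 (-1.89), CDC45 (0.19), PTTG1 (3.87) and ATP5F1A (-3.70) for HuR siRNA, and PTTG1 (-3.32) and UQCRC1 (0.53) in the background. On fragment mass they were FBLN2 (-0.0080) for AUF1 siRNA and CAV2 (-0.24) for HuR siRNA. With the other PDL 15 library as the control they were NFKBIA (0.14), RPS15A (1.32), RPS9 (0.39) and RPL3 (0.42) for PDL 55. For AUF1 siRNA they were HIST1H2BL (1.004), HIST1H2AD (0.92), PLK2 (-1.01), TNC (-0.92), FBLN2 (-0.70), FLNA (-0.48), TGFBI (-0.042) and PDLIM7 (-0.44). For HuR siRNA they were PTTG1 (1.12), UBE2C (0.97), HIST1H2BL (0.35), HIST1H2AD (0.29), TNC (-0.45), COL12A1 (-0.45), RPL4 (-0.48), RPL7A (-0.89) and RPS14 (-0.52). Genes less than 2-fold apart as deposited that changed sign were LIG1 (0.28) and CCND2 (0.96) for HuR siRNA and ELAVL1 (0.049) for PDL 55 with that control, NDUFC2 (-0.27) for PDL 55 and PFKP (-1.73) in the background with 1 transcript per gene, and PFKP (-0.48) on fragment mass. Without LOWDATA transcripts they were HMGB2 (0.072) for HuR siRNA, FDPS (-0.00074) and KRT19 (-0.27) for AUF1 against HuR siRNA and DUSP5 (-0.27) in the background, and with quantile normalization ELAVL1 (0.00071) in the background.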

Other observations

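The genes named in the next paragraph and the grouping of genes by length were chosen after their values were seen.

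Some single chromatin and cell cycle genes outside the naming rule differed at PDL 55, while the fixed list of cell cycle regulators did not stand apart (-0.31, percentile 2.66). Relative to the median gene, 4 of the 23 measured genes of that list were at least 2-fold higher and 5 lower. The nuclear lamina gene LMNB1 (0.893 FPKM against 33.1), the chromatin genes HMGB2 (2.68 FPKM against 29.5) and EZH2 (1.46 FPKM against 10.8), and the retinoblastoma relative RBL1 (1.64 FPKM against 8.11) were lower there, while E2F7 (log2 ratio 2.42 relative to the median gene) and the cyclin CCND3 (26.9 FPKM against 6.79) were higher. In the control siRNA library, LMNB1 was at 20.6, HMGB2 at 39.0, EZH2 at 7.01, RBL1 at 4.44 and CCND3 at 9.52. Among secreted factors, CCL2 (90.3 FPKM against 15.2) and SERPINE2 (145 FPKM against 26.1) were higher at PDL 55 and CXCL12 (0.920 FPKM against 21.5) and ICAM1 (3.36 FPKM against 19.5) lower.

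Genes that span at least 500 kb, such as FHIT, had negative median ratios in both knockdown libraries against the control siRNA library. This group was not set beside matched random lists. Of 251 such genes, 110 were at least 2-fold lower and 1 higher relative to the median with AUF1 siRNA, and 92 and 2 with HuR siRNA, with medians of -0.79 and -0.48. In control siRNA against PDL 15, 102 were higher and 11 lower, with a median of 0.57. The medians were -0.059 for AUF1 against HuR siRNA and 0.080 for PDL 55 against PDL 15.

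Small RNA genes, left out of the comparisons because FPKM is unreliable for features shorter than a fragment, numbered 215. Of these, 17 were at least 2-fold higher and 33 lower at PDL 55, 46 and 76 with AUF1 siRNA, 58 and 73 with HuR siRNA, 17 and 20 for AUF1 against HuR siRNA, and 75 and 51 for control siRNA against PDL 15. In the same order, 37, 66, 67, 37 and 68 of the small RNA genes were listed at 0 in at least 1 of the libraries compared, which can be a failed estimate.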
